A study of Mus musculus with 10 samples.

How the data were processed

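Hearts of 10 male C57BL/6 mice of 10 weeks, 5 given PBS and 5 given LPS at 10 mg/kg into the peritoneum, were taken 12 h after injection, and each gave 1 mRNA library sequenced on a DNA nanoball instrument. Per the labels, messenger RNA was enriched from RNA samples that had passed a quality check. Groups and replicate numbers were taken from the labels, and 0 columns of the table could not be matched to a sample. The labels do not say that equal replicate numbers mark a shared cage, litter or day.

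The deposited table gives, per gene and mouse, an estimated read count, a TPM value and an FPKM value that the authors computed. Per the submitters' processing notes the genome build was GRCm39, and the aligner, the counting program and its handling of strand and of reads with several matches are not given in the sources used here. Of the deposited estimated counts above 0, 87.2% to 88.2% in each library lay within 1e-09 of a whole number, and all were rounded before testing. The deposited TPM values sum to 1000000 in each library, and the FPKM values do not. Of 17642 genes, 17512 had a gene ID in a RefSeq table of assembly GRCm38.p6, which differs from the build used, so that it served for names only and no coordinates are given. 0 mitochondrially encoded genes were among them, so that this class and the planned share of counts without it are not analysed here. Close copies such as the metallothionein, guanylate-binding protein, Serpina3, H2 and globin genes can share reads, and their counts are uncertain, as are those of antisense and overlapping genes.

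Totals ran from 11868340 to 14048111 estimated counts per library, and the 10 most abundant genes held 9.1% to 13.2% of each. Genes were kept by filterByExpr, scaled by the trimmed mean of M values and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on group alone, two-sided, with Benjamini-Hochberg adjustment over 13186 genes. The standard error is the log2 fold change divided by the square root of its F statistic. Levels are CPM from the scaled library sizes, and log2 CPM in the principal components and list means used a prior count of 2. The biological coefficient of variation from the common dispersion was 0.203.

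Before the data were examined, 34 gene lists and 22 lists of cell type markers or of tissue that dissection can carry over were fixed, along with the tests, the alternatives and the rule for naming genes. 1201 listed genes were in the table, 8 of them found through a synonym. Lists with at least 5 tested members were tested by camera (limma 3.58.1, voom values, preset inter-gene correlation 0.01, two-sided), adjusted over the gene lists and over the marker lists separately. Members were counted from the gene test, both over all genes and adjusted over the list alone. The rule named the 12 largest increases and decreases among called genes with groups fully apart, a mean of at least 5 CPM and a symbol that is not a predicted name. It also named up to 4 called members of each list with the largest change, of which at most 3 in 1 direction where both occurred, the most abundant member of a list with no call, and 18 genes fixed by name, in all 212 genes, of which some are not reported here. The position of PBS 3 in a list is the difference of its mean log2 CPM from the other 4 PBS libraries as a percent of that of the LPS mean, given where the latter is at least 0.5.

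Shares of counts and the distances of libraries from their group centre were compared by exact permutation over all assignments, two-sided. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom from 8.12 to 111.7 between pairs, so that all 10 libraries were counted separately. Alternatives were DESeq2 1.42.0, voom with sample weights, other scalings, other filters (none, or 1 CPM in 5 samples), an adjusted p of 0.01, a fold threshold, limma on log2(TPM + 1), log2(TPM + 0.1) and log2(FPKM + 1) over genes of at least 1 in 5 samples, a replicate block, an estimated inter-gene correlation, fry, lists without shared members, and each library left out in turn. The scripts were tested on simulated counts over 13186 genes. There, 50 genes were changed 1.5-fold, 100 genes 2-fold and 50 genes 4-fold. Of these, 40%, 69% and 96% were called, with 5 false calls. In the real data 58.6% of the tested genes were called, so that these rates need not hold there. Where nothing changed, 0 genes and 0 lists were called. The 0 lists cannot be carried over to the real data, whose correlation between genes the simulation was not shown to match. With a correlation estimated from the real data, 0 of the 17 gene lists called by camera stayed called.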

Results

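The hearts of 10 male wild-type C57BL/6 mice were profiled by mRNA sequencing to model the myocardial dysfunction that accompanies sepsis. Lipopolysaccharide (LPS), a cell wall component of Gram-negative bacteria that activates innate immunity, was given to 5 mice as 1 intraperitoneal dose of 10 mg/kg, and 5 control mice received phosphate-buffered saline (PBS). Tissue was taken 12 h later. Each mouse gave 1 library, so that the spread within a group is a spread between animals. The libraries held 11868340 to 14048111 estimated counts each, with 15477 to 15740 genes above 0, and the groups overlapped in both. The design gives 1 comparison, LPS against PBS, which asks which cardiac genes change in this model. Below, values after a gene are its log2 fold change ± SE (n = 5 per group, edgeR quasi-likelihood fit), levels are mean ± SD in CPM (counts scaled by the effective library size), and a gene is said to rise or fall only where its Benjamini-Hochberg adjusted p over all tested genes was under 0.05.

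Csf3, which encodes granulocyte colony-stimulating factor (gene ID 12985), went from 0.31 ± 0.389 CPM in PBS to 87 ± 38.8 CPM in LPS hearts (adjusted p = 1.19e-06). Lcn2, an iron-sequestering antibacterial protein (gene ID 16819), went from 114 ± 234 CPM in PBS to 2649 ± 425 CPM in LPS hearts, and Cxcl10, an interferon-induced chemokine (gene ID 15945), from 4.91 ± 8.9 CPM in PBS to 293 ± 119 CPM in LPS hearts. In the other direction, Slc26a10 (gene ID 216441), a member of an anion transporter family, went from 57.6 ± 11.4 CPM in PBS to 0.382 ± 0.278 CPM in LPS hearts (adjusted p = 9.56e-08), and Asb2 (gene ID 65256), which encodes a subunit of ubiquitin ligases in muscle, from 416 ± 139.5 CPM in PBS to 12.9 ± 3.5 CPM in LPS hearts. By the rule set out for naming genes, the 12 with the greatest increases were Csf3 (8.05 ± 0.57), Ptx3 (6.76 ± 0.96), Serpina3f (6.54 ± 0.92), Fgf23 (6.38 ± 0.62), Lipg (6.18 ± 0.39), Sh2d5 (6.02 ± 0.30), Calhm6 (5.95 ± 0.41), Ubd (5.95 ± 0.60), Cxcl5 (5.92 ± 0.83), Cxcl10 (5.86 ± 0.96), AA467197 (5.84 ± 0.45) and Il6 (5.70 ± 0.75). The 12 with the greatest decreases were Stmn2 (-7.55 ± 0.68), Slc26a10 (-7.19 ± 0.30), Ky (-6.14 ± 0.36), Inmt (-5.97 ± 0.68), Asb2 (-5.01 ± 0.32), Srrm4 (-4.77 ± 0.47), Klhdc8a (-4.63 ± 0.62), Hey1 (-4.57 ± 0.26), Arhgef19 (-4.52 ± 0.42), Colq (-4.52 ± 0.44), Lingo3 (-4.40 ± 0.48) and Aplnr (-4.26 ± 0.38). Among these, Fgf23 encodes a phosphate-regulating hormone, Hey1 a transcription factor of the Notch pathway and Aplnr the apelin receptor. Reads of Serpina3f can be shared with neighbouring members of its family, so that its level is uncertain.

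In all, 13186 genes were tested, of which 3806 rose, 3916 fell and 5464 did not pass. With an absolute log2 fold change of at least 1 as well, 1325 rose and 1602 fell. All 5 LPS values lay above all 5 PBS values in 2887 genes and below them in 2805, together 43.2% of the tested genes, where chance gives 0.794%. The balance of directions depended on scaling: 49.3% of the calls were increases with trimmed-mean scaling, 38.6% with upper-quartile scaling (3068 higher, 4874 lower) and 35.5% with library totals only (2764 higher, 5019 lower), which moved the median of all genes by -0.13 and -0.15 on the log2 scale.

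1 control library, PBS 3, stood apart from the other 4. On the component that held 79.5% of the variance it lay at -15.4, where the other PBS libraries lay between -78.1 and -68.4 and the LPS libraries between 53.9 and 67.9. Its mean correlation with the other PBS libraries was 0.946 and with the LPS libraries 0.936 (Pearson, across genes, which are not independent replicates), where the other PBS libraries had 0.971 to 0.974 and 0.853 to 0.868. Lcn2 was at 532 CPM in PBS 3 and between 2.38 and 15.6 CPM in the other PBS hearts, and Pdk4, a kinase that restrains glucose oxidation, was at 2854 CPM against 141 to 269 CPM. Leaving out each library in turn was planned, while giving every list again without PBS 3 was chosen after its values were seen. The median given for a list is that of its log2 fold changes, and PBS 3 at a percent is how far it stood from the mean log2 CPM of the other 4 PBS libraries on the way to that of LPS. Where LPS differed from those 4 by under 0.5 and PBS 3 by at least 0.25, both shifts in mean log2 CPM stand in its place. Without PBS 3, 4284 of 13301 genes rose and 4146 fell, and 7518 genes were called in the same direction in both fits and 0 in opposite directions. The log2 fold changes of some genes raised in PBS 3 grew by over 1.5 times when it was left out. These became 8.19 for Lcn2, 9.89 for Serpina3f, 5.06 for Pdk4, 6.51 for Angptl4, 6.61 for Ccl5 and 5.35 for Hp. Others grew by less, as the median of the interferon-stimulated list was 2.52 with all libraries and 3.24 without PBS 3.

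**Figure D1:**
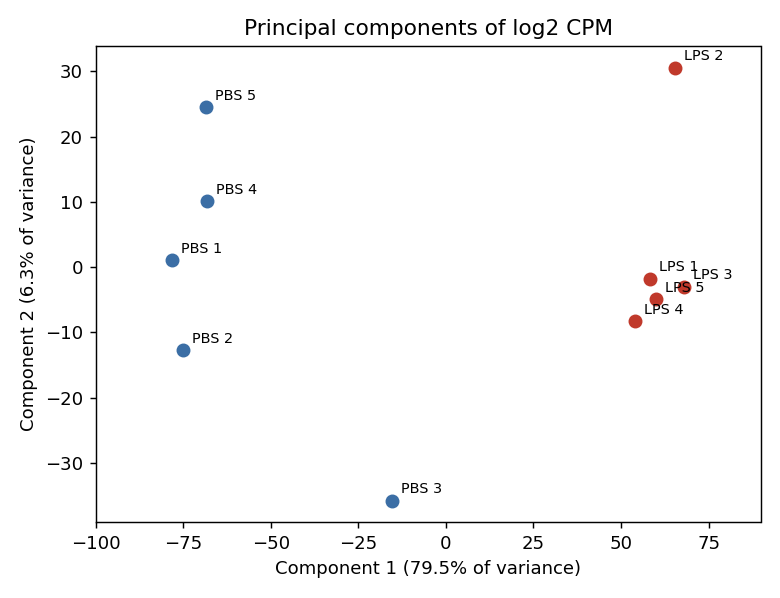
Principal components of log2 CPM over the 13186 tested genes, with 1 point per library, PBS in blue and LPS in red. Component 1 (horizontal, 79.5% of the variance) separates the groups, and PBS 3 lies between them. Component 2 (vertical) holds 6.3%.

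Most tested cytokine, acute-phase and interferon-stimulated genes rose, and PBS 3 was raised for each of these lists. 23 of 32 tested cytokine and chemokine genes rose, 2 fell and 7 did not pass (25 and 2 adjusted over the list alone). Cytokine and chemokine genes had a median of 2.24 (camera adjusted p = 7.88e-06, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 68%, and 29 rose and 3 fell of 35 without PBS 3, with a median of 4.03. Besides Csf3, Cxcl5 and Cxcl10, Il6 was at 0.53 ± 0.808 CPM in PBS and 29.6 ± 22.1 CPM in LPS hearts. Among the falling members was Ccl6 (-2.51 ± 0.46). Il1b (1.12 ± 0.59, adjusted p = 0.125) and Tnf (1.37 ± 0.56, adjusted p = 0.0515), both classical inflammatory cytokines, did not pass, with 3.4 ± 3.88 CPM in PBS and 7.47 ± 1.79 CPM in LPS hearts and 1.15 ± 1.43 CPM in PBS and 3.06 ± 0.727 CPM in LPS hearts. Without PBS 3, where they stood at 10.0 and 3.71 CPM, both passed (2.12, adjusted p = 0.000618, and 2.57, adjusted p = 7.59e-06). Tnf also passed without LPS 1 (adjusted p = 0.0476), in DESeq2 (adjusted p = 0.0207) and in voom with sample weights (adjusted p = 8.86e-05), where Il1b passed too (adjusted p = 0.000788). 24 of 27 tested acute-phase and antimicrobial genes rose, 0 fell and 3 did not pass (24 and 0 adjusted over the list alone). Acute-phase and antimicrobial genes had a median of 3.11 (camera adjusted p = 3.07e-09, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 63%, and 26 rose and 0 fell of 28 without PBS 3. Examples besides Ptx3 were Lcn2 (4.54 ± 1.35), Hamp (6.06 ± 0.61) and Serpina3g (4.98 ± 0.74), where Hamp encodes the iron regulator hepcidin. 47 of 49 tested interferon-stimulated genes rose, 0 fell and 2 did not pass (48 and 0 adjusted over the list alone). Interferon-stimulated genes had a median of 2.52 (camera adjusted p = 1.74e-13, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 71%, and 48 rose and 0 fell of 49 without PBS 3. The guanosine triphosphatases of cell-autonomous immunity were among the highest, with Igtp (5.01 ± 0.81), Iigp1 (4.45 ± 0.87), Gbp6 (4.29 ± 0.79) and Irgm1 (4.26 ± 0.57), and Iigp1 stood at 250.4 ± 397 CPM in PBS and 5462 ± 1065 CPM in LPS hearts. Gbp6, Iigp1 and Serpina3g belong to families of close copies, so that their counts are uncertain.

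20 of 27 tested antigen presentation and immunoproteasome genes rose, 5 fell and 2 did not pass (20 and 6 adjusted over the list alone). Antigen presentation and immunoproteasome genes had a median of 1.60 (camera adjusted p = 0.000217, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 54%, and 20 rose and 7 fell of 27 without PBS 3. The peptide transporter gene Tap1 (3.52 ± 0.56), the class I regulator Nlrc5 (3.45 ± 0.60) and Tapbpl (2.39 ± 0.32) rose, and H2-DMb1 (-1.41 ± 0.35), of the class II pathway, fell. 27 of 36 tested Toll-like receptor and NF-kB genes rose, 1 fell and 8 did not pass (27 and 1 adjusted over the list alone). Toll-like receptor and NF-kB genes had a median of 1.21 (camera adjusted p = 2.32e-07, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 60%, and 27 rose and 1 fell of 36 without PBS 3. Nfkbiz (3.36 ± 0.34), which encodes a nuclear IkB protein that takes part in the induction of secondary NF-kB targets, and the feedback inhibitors Tnfaip3 (3.07 ± 0.48) and Zc3h12a (2.97 ± 0.27) rose with the LPS receptor genes Tlr4 (1.15 ± 0.20) and Cd14 (1.17 ± 0.24), while Tnip3 (-0.78 ± 0.24) fell. 20 of 31 tested JAK-STAT genes rose, 5 fell and 6 did not pass (20 and 5 adjusted over the list alone). JAK-STAT genes had a median of 0.89 (camera adjusted p = 0.000695, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 49%, and 21 rose and 5 fell of 31 without PBS 3. The suppressors of cytokine signalling Socs1 (4.55 ± 0.39) and Socs3 (4.03 ± 0.55) and the receptor subunit Il18rap (3.65 ± 0.35) rose, and the interferon gamma receptor subunit Ifngr2 (-1.14 ± 0.15) fell. 14 of 24 tested inflammasome, pyroptosis and necroptosis genes rose, 1 fell and 9 did not pass (14 and 1 adjusted over the list alone). Inflammasome, pyroptosis and necroptosis genes had a median of 1.01 (camera adjusted p = 0.000695, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 66%, and 15 rose and 1 fell of 24 without PBS 3. Increases included Casp4 (3.22 ± 0.40), Mlkl (2.63 ± 0.33) and Mefv (2.0 ± 0.58), where Casp4 encodes a sensor of intracellular LPS and Mlkl the effector of necroptosis, and the decrease was Fadd (-0.41 ± 0.11).

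Complement, coagulation and nitric oxide genes moved in both directions. 5 of 22 tested complement genes rose, 5 fell and 12 did not pass (5 and 5 adjusted over the list alone). Complement genes had a median of 0.24 (camera adjusted p = 0.816), with a shift of 0.75 in PBS 3 and 0.42 in LPS, and 11 rose and 5 fell of 22 without PBS 3. With library totals 4 rose and 7 fell. Increases were seen for Masp1 (1.93 ± 0.27) and C1ra (1.80 ± 0.32), and decreases for Cd55 (-2.15 ± 0.14) and C3ar1 (-2.10 ± 0.21). 15 of 29 tested endothelial activation and adhesion genes rose, 6 fell and 8 did not pass (15 and 6 adjusted over the list alone). Endothelial activation and adhesion genes had a median of 0.64 (camera adjusted p = 0.0688), with PBS 3 at 64%, and 16 rose and 6 fell of 29 without PBS 3. The list passed without PBS 3 (adjusted p = 0.0369), with upper-quartile scaling (adjusted p = 0.0284) and with no filter on low counts (adjusted p = 0.0262), but not with an estimated correlation (adjusted p = 0.495, and adjusted p = 0.248 without PBS 3). The leukocyte adhesion genes Selp (4.74 ± 0.70) and Icam1 (2.75 ± 0.48) and the chemokine-binding receptor Ackr1 (3.17 ± 0.69) rose, and Tek (-1.70 ± 0.12), the angiopoietin receptor, fell. 10 of 20 tested coagulation and fibrinolysis genes rose, 5 fell and 5 did not pass (10 and 5 adjusted over the list alone). Coagulation and fibrinolysis genes had a median of 0.32 (camera adjusted p = 0.193), with PBS 3 at 54%, and 11 rose and 5 fell of 21 without PBS 3. With no filter on low counts the list passed (adjusted p = 0.0262), but not with an estimated correlation (adjusted p = 0.666, and adjusted p = 0.514 without PBS 3). The urokinase receptor Plaur (4.31 ± 0.38) and F10 (2.75 ± 0.43) rose, while urokinase itself, Plau (-3.03 ± 0.24), fell. 10 of 28 tested nitric oxide, arginine and polyamine genes rose, 8 fell and 10 did not pass (10 and 9 adjusted over the list alone). Nitric oxide, arginine and polyamine genes had a median of -0.11 (camera adjusted p = 0.992), and 9 rose and 9 fell of 28 without PBS 3. With upper-quartile scaling 9 rose and 12 fell, and with library totals 9 rose and 13 fell. The median was below 0 while camera and the mean of 0.08 pointed upwards. The arginine transporter Slc7a2 (3.14 ± 0.35) and the inducible synthase Nos2 (1.55 ± 0.26) rose, and Gucy1b1 (-1.92 ± 0.15), Pde5a (-2.01 ± 0.21) and Gatm (-1.97 ± 0.22), of which the guanylate cyclase subunit Gucy1b1 responds to nitric oxide, fell.

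Among genes of energy metabolism, 0 of 45 tested members of the fixed list of nuclear-encoded respiratory chain genes passed in edgeR and 0 in DESeq2, 2 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. Listed respiratory chain genes had a median of -0.10 (camera adjusted p = 0.346), with a shift of -0.50 in PBS 3 and -0.21 in LPS, and a median of -0.19 without PBS 3. With upper-quartile scaling 0 rose and 3 fell, and with library totals 0 rose and 9 fell. The most abundant of them, Atp5b, was at 6236 ± 499 CPM in PBS and 6599 ± 455 CPM in LPS hearts. Without PBS 3, 0 rose, 4 fell and the list passed (adjusted p = 0.0469), but not with an estimated correlation (adjusted p = 0.925 with all libraries, and adjusted p = 0.773 without PBS 3). 7 of 45 tested fatty acid uptake and oxidation genes rose, 7 fell and 31 did not pass (5 and 6 adjusted over the list alone). Fatty acid uptake and oxidation genes had a median of -0.07 (camera adjusted p = 0.789), with a shift of 0.50 in PBS 3 and 0.27 in LPS, and 12 rose and 8 fell of 45 without PBS 3, with a median of -0.02. With upper-quartile scaling 5 rose and 13 fell, and with library totals 5 rose and 15 fell. The median and camera lay below 0 and the mean above it (0.08). Pdk4 (3.22 ± 0.81) rose from 736 ± 1185 CPM in PBS to 6845 ± 638 CPM in LPS hearts, the lipase inhibitor Angptl4 (3.87 ± 1.00) and the uncoupling protein Ucp3 (1.86 ± 0.41) also rose, and Ppargc1a (-1.87 ± 0.14), a coactivator of mitochondrial gene expression, fell. Cpt1b, the muscle form of the enzyme that commits fatty acids to mitochondrial import, was at 632 ± 100.2 CPM in PBS and 565 ± 46 CPM in LPS hearts and did not pass (adjusted p = 0.277). 1 of 42 tested tricarboxylic acid cycle and branched-chain oxidation genes rose, 8 fell and 33 did not pass (1 and 4 adjusted over the list alone). Tricarboxylic acid cycle and branched-chain oxidation genes had a median of -0.15 (camera adjusted p = 0.13), with a shift of -0.25 in PBS 3 and -0.20 in LPS, and 2 rose and 16 fell of 42 without PBS 3. With upper-quartile scaling 1 rose and 21 fell, and with library totals 1 rose and 23 fell. The list passed without PBS 3 (adjusted p = 0.0407), without LPS 2 (adjusted p = 0.0392) and with upper-quartile scaling (adjusted p = 0.0284), but not with an estimated correlation (adjusted p = 0.716, and adjusted p = 0.539 without PBS 3). Ppm1k (-0.87 ± 0.19), Mmut (-0.57 ± 0.12) and Bdh1 (-0.57 ± 0.22) fell and Pcx (0.70 ± 0.15) rose. The call of Bdh1 was lost without PBS 1, PBS 2, LPS 1, LPS 2 or LPS 5 (adjusted p from 0.0655 to 0.104). 10 of 35 tested glycolysis and glucose genes rose, 12 fell and 13 did not pass (10 and 12 adjusted over the list alone). Glycolysis and glucose genes had a median of 0.03 (camera adjusted p = 0.799), and 11 rose and 15 fell of 35 without PBS 3. That median turned to -0.10 with upper-quartile scaling. The glucose and lactate transporters Slc2a1 (2.14 ± 0.18) and Slc16a3 (2.45 ± 0.42) and Pfkfb3 (3.58 ± 0.30) rose, whereas the cardiac isoform Pfkfb2 (-2.58 ± 0.16) fell. 2 of 31 tested mitochondrial dynamics and quality control genes rose, 13 fell and 16 did not pass (2 and 10 adjusted over the list alone). Mitochondrial dynamics and quality control genes had a median of -0.19 (camera adjusted p = 0.0584), and 3 rose and 13 fell of 31 without PBS 3. That list passed without PBS 3, LPS 1 or LPS 2 (adjusted p from 0.027 to 0.0494), with upper-quartile scaling (adjusted p = 0.0279) and with no filter (adjusted p = 0.0389), but not with an estimated correlation (adjusted p = 0.666, and adjusted p = 0.481 without PBS 3). Mtfp1 (-2.15 ± 0.29), Ppif (-0.92 ± 0.13) and Sirt3 (-0.82 ± 0.16) fell and Clpx (0.70 ± 0.19) rose. Of the fixed list of 15 mitochondrially encoded genes, 0 were in the table used, and that list is not analysed here.

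**Figure D2:**
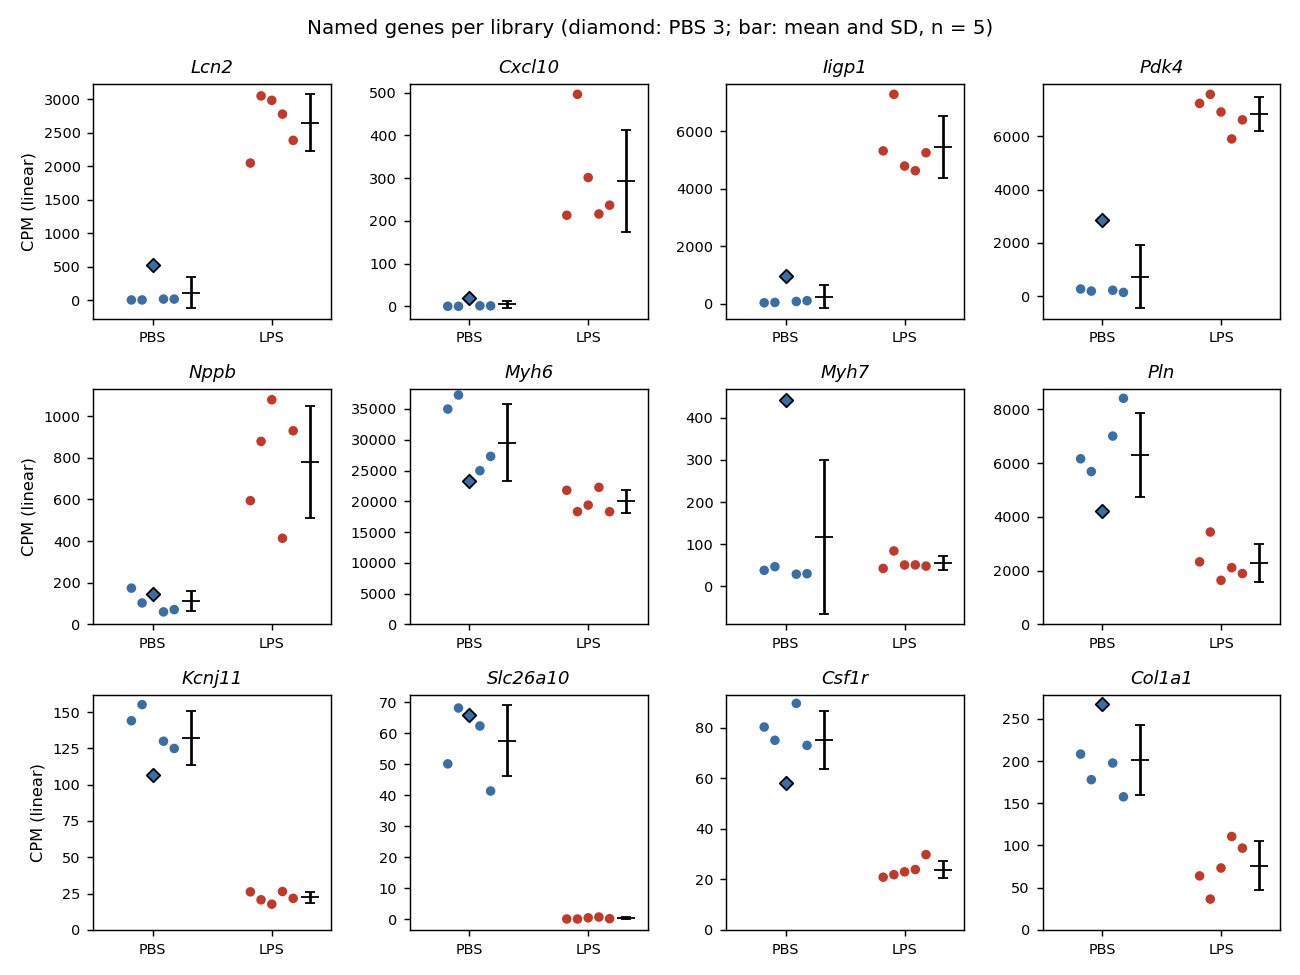
Levels of 12 named genes in each library, in CPM on linear axes that differ between panels. Points are libraries (PBS blue, LPS red, PBS 3 as a diamond) and bars are the mean and SD (n = 5). Slc26a10 separates the groups with PBS 3 among the controls, whereas PBS 3 exceeds the other PBS hearts for Lcn2 and Pdk4 and all 9 other hearts for Myh7.

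Most tested genes of ion channels and of calcium cycling fell. 5 of 35 tested ion channel and conduction genes rose, 25 fell and 5 did not pass (5 and 25 adjusted over the list alone). Ion channel and conduction genes had a median of -0.89 (camera adjusted p = 0.000254, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 45%, and 6 rose and 25 fell of 35 without PBS 3. The potassium channel genes Kcnj3 (-2.62 ± 0.22), Kcnj11 (-2.55 ± 0.14) and Kcnj5 (-2.54 ± 0.20) fell, with Kcnj11, the pore of the cardiac ATP-sensitive channel, at 132 ± 18.5 CPM in PBS and 22.5 ± 3.73 CPM in LPS hearts. 4 of 29 tested calcium handling genes rose, 18 fell and 7 did not pass (4 and 18 adjusted over the list alone). Calcium handling genes had a median of -0.33 (camera adjusted p = 0.0159, and adjusted p = 0.391 with an estimated correlation), with a shift of -0.29 in PBS 3 and -0.48 in LPS, and 4 rose and 16 fell of 29 without PBS 3. With upper-quartile scaling 1 rose and 19 fell, and with library totals 1 rose and 19 fell. Jph2 (-1.73 ± 0.21), Pln (-1.47 ± 0.22) and Cacnb2 (-1.46 ± 0.21) fell and Camk2d (0.82 ± 0.12) rose. Pln, the inhibitor of the sarcoplasmic reticulum calcium pump, was at 6295 ± 1561 CPM in PBS and 2281 ± 695 CPM in LPS hearts. The pump gene itself, Atp2a2 (-0.27 ± 0.10), was at 13440 ± 1254 CPM in PBS and 11140 ± 542 CPM in LPS hearts, and its call was lost without PBS 1, PBS 2, PBS 4, PBS 5, LPS 3, LPS 4 or LPS 5 (adjusted p from 0.0524 to 0.0881) and with no filter on low counts (adjusted p = 0.0765). 3 of 29 tested adrenergic and cyclic nucleotide genes rose, 17 fell and 9 did not pass (3 and 17 adjusted over the list alone). Adrenergic and cyclic nucleotide genes had a median of -0.41 (camera adjusted p = 0.0415, and adjusted p = 0.391 with an estimated correlation), and 5 rose and 17 fell of 29 without PBS 3. The call of this list was lost without PBS 2 (adjusted p = 0.0517) and without LPS 3 (adjusted p = 0.0502). The phosphodiesterase Pde4b (3.26 ± 0.17) and Rgs16 (2.28 ± 0.24) rose and Prkar2b (-1.73 ± 0.43) and Rgs2 (-1.48 ± 0.27) fell. 4 of 34 tested sarcomere genes rose, 12 fell and 18 did not pass (4 and 12 adjusted over the list alone). Sarcomere genes had a median of -0.20 (camera adjusted p = 0.227), and 6 rose and 16 fell of 34 without PBS 3. Myh7b (-4.00 ± 0.40) and Myl7 (-4.10 ± 0.67) fell, and the stress-responsive Ankrd1 (3.09 ± 0.58) and Xirp1 (2.09 ± 0.17) rose. The main cardiac myosin heavy chain gene, Myh6 (-0.56 ± 0.15), was at 29550 ± 6229 CPM in PBS and 20010 ± 1896 CPM in LPS hearts. Myh7, the slow isoform, was at 117 ± 182 CPM in PBS and 55.1 ± 16.5 CPM in LPS hearts and did not pass (-1.09 ± 0.73, adjusted p = 0.22). PBS 3 held 442 CPM of Myh7 and the other PBS hearts 28.8 to 46.6, and without PBS 3 Myh7 rose (0.63, adjusted p = 0.0159). 12 of 20 tested wall-stress and fetal programme genes rose, 1 fell and 7 did not pass (12 and 1 adjusted over the list alone). Wall-stress and fetal programme genes had a median of 1.12 (camera adjusted p = 0.000952, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 66%, and 13 rose and 1 fell of 20 without PBS 3. The natriuretic peptide gene Nppb (2.82 ± 0.34) rose from 111 ± 48.6 CPM in PBS to 779 ± 269.6 CPM in LPS hearts, whereas Nppa was at 72 ± 33.6 CPM in PBS and 74.4 ± 42.1 CPM in LPS hearts and did not pass (0.05 ± 0.42, adjusted p = 0.932). Rcan1 (3.96 ± 0.19), Myc (3.71 ± 0.48) and Gdf15 (3.53 ± 0.44) rose and Acta1 (-0.82 ± 0.25) fell. 5 of 25 tested cardiac transcription factor genes rose, 15 fell and 5 did not pass (6 and 15 adjusted over the list alone). Cardiac transcription factor genes had a median of -0.41 (camera adjusted p = 0.0415, and adjusted p = 0.391 with an estimated correlation), and 7 rose and 16 fell of 25 without PBS 3. The call of that list was lost without PBS 2 (adjusted p = 0.0535), PBS 3 (adjusted p = 0.0581) and LPS 5 (adjusted p = 0.0627), and where members in more than 1 list were left out (adjusted p = 0.0512). The oestrogen-related receptors, regulators of energy metabolism, fell: Esrrg (-1.90 ± 0.21), Esrrb (-1.88 ± 0.22) and Esrra (-1.07 ± 0.13), and Irx3 (0.92 ± 0.21) rose.

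In several lists of stress response genes more members rose than fell. 19 of 34 tested oxidative stress and metallothionein genes rose, 2 fell and 13 did not pass (19 and 2 adjusted over the list alone). Oxidative stress and metallothionein genes had a median of 0.59 (camera adjusted p = 0.000435, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 43%, and 20 rose and 2 fell of 34 without PBS 3. With library totals 15 rose and 4 fell. The metallothioneins Mt2 (5.37 ± 0.93) and Mt1 (3.77 ± 0.54), which bind zinc and copper, and haem oxygenase, Hmox1 (3.74 ± 0.31), rose, and Nox4 (-0.96 ± 0.36) fell, a call lost without PBS 2, PBS 4, PBS 5, LPS 2, LPS 3 or LPS 4 (adjusted p from 0.0655 to 0.0831). 13 of 27 tested iron, ferroptosis and cuproptosis genes rose, 5 fell and 9 did not pass (15 and 5 adjusted over the list alone). Iron, ferroptosis and cuproptosis genes had a median of 0.39 (camera adjusted p = 0.0225, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 34%, and 15 rose and 5 fell of 27 without PBS 3. Ptgs2 (3.63 ± 0.63), Slc39a14 (3.29 ± 0.21) and Alox15 (2.30 ± 0.23) rose, and that list was not called where members in more than 1 list were left out (adjusted p = 0.0876). The transferrin receptor Tfrc (-1.51 ± 0.49) fell, a call lost without PBS 1 or PBS 5 (adjusted p from 0.0555 to 0.0562). 15 of 32 tested unfolded protein and integrated stress response genes rose, 3 fell and 14 did not pass (15 and 3 adjusted over the list alone). Unfolded protein and integrated stress response genes had a median of 0.42 (camera adjusted p = 0.0133, and adjusted p = 0.667 with an estimated correlation), with PBS 3 at 98%, and 23 rose and 2 fell of 32 without PBS 3. With library totals 10 rose and 4 fell. Atf4, the transcription factor of the integrated stress response, and its target Asns rose, as Atf4 (1.63 ± 0.14) and Asns (2.39 ± 0.31), and Herpud1 (-1.14 ± 0.13), of the endoplasmic reticulum, fell. 19 of 26 tested glucocorticoid-responsive genes rose, 1 fell and 6 did not pass (19 and 1 adjusted over the list alone). Glucocorticoid-responsive genes had a median of 2.23 (camera adjusted p = 1.27e-06, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 67%, and 24 rose and 1 fell of 26 without PBS 3. With the correlation estimated without PBS 3 it was the 1 list of 33 that passed (adjusted p = 0.021). Angptl4, Lcn2 and Mt2 were its largest increases, and the receptor gene Nr3c1 (-0.66 ± 0.09) fell. 23 of 34 tested apoptosis and p53 target genes rose, 7 fell and 4 did not pass (23 and 7 adjusted over the list alone). Apoptosis and p53 target genes had a median of 0.92 (camera adjusted p = 0.000217, and adjusted p = 0.391 with an estimated correlation), with PBS 3 at 47%, and 23 rose and 7 fell of 34 without PBS 3. Gadd45g (3.78 ± 0.24), Cdkn1a (3.63 ± 0.48) and Bcl2l1 (2.59 ± 0.26) rose and Sesn1 (-0.84 ± 0.19) fell, where Bcl2l1 encodes an inhibitor and Cdkn1a a cell cycle arrest protein.

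Hypoxia, chaperone, autophagy, clock, matrix and cell cycle genes changed in both directions, and their lists did not pass camera. By fry, which tests a list by itself, the hypoxia (adjusted p = 5.52e-05) and chaperone lists (adjusted p = 0.00684) passed as higher. The clock list passed by fry as lower (adjusted p = 0.00874). 12 of 25 tested hypoxia-inducible genes rose, 7 fell and 6 did not pass (12 and 7 adjusted over the list alone). Hypoxia-inducible genes had a median of 0.24 (camera adjusted p = 0.135), and 13 rose and 8 fell of 25 without PBS 3. With Slc2a1 and Pfkfb3, Nampt (1.78 ± 0.20) rose, and Ankrd37 (-0.99 ± 0.18) fell. 11 of 25 tested heat shock and chaperone genes rose, 3 fell and 11 did not pass (11 and 3 adjusted over the list alone). Heat shock and chaperone genes had a median of 0.17 (camera adjusted p = 0.17), and 10 rose and 3 fell of 25 without PBS 3. With upper-quartile scaling 9 rose and 6 fell, and with library totals 8 rose and 7 fell. Hspb1 (2.06 ± 0.21), Dnajb4 (1.23 ± 0.19) and Hsp90aa1 (0.94 ± 0.12) rose and Hspb3 (-1.29 ± 0.38) fell. 9 of 31 tested autophagy, mitophagy and ubiquitin ligase genes rose, 6 fell and 16 did not pass (8 and 3 adjusted over the list alone). Autophagy, mitophagy and ubiquitin ligase genes had a median of 0.17 (camera adjusted p = 0.358), with a shift of 0.29 in PBS 3 and 0.22 in LPS, and 12 rose and 5 fell of 31 without PBS 3. With upper-quartile scaling 5 rose and 8 fell, and with library totals 5 rose and 9 fell. The muscle atrophy ligase Fbxo32 (1.59 ± 0.34), Lamp2 (0.76 ± 0.16) and Ctsl (0.74 ± 0.21) rose, and the lysosomal regulator Tfeb (-1.34 ± 0.11) fell. 6 of 20 tested clock genes rose, 8 fell and 6 did not pass (6 and 8 adjusted over the list alone). Clock genes had a median of 0.04 (camera adjusted p = 0.576), and 6 rose and 8 fell of 20 without PBS 3, with a median of 0.00. Their median turned to -0.08 with upper-quartile scaling, and camera and the mean (-0.30) pointed downwards. Hlf (-2.90 ± 0.24), Per3 (-2.77 ± 0.21) and Dbp (-2.15 ± 0.42) fell and Per1 (1.61 ± 0.34) rose. 18 of 45 tested extracellular matrix genes rose, 16 fell and 11 did not pass (19 and 16 adjusted over the list alone). Extracellular matrix genes had a median of 0.21 (camera adjusted p = 0.73), with PBS 3 at 85%, and 20 rose and 15 fell of 45 without PBS 3. The proteases Adamts4 (5.04 ± 0.68) and Adamts1 (3.21 ± 0.35) and Thbs4 (3.60 ± 0.47) rose and Col5a1 (-2.01 ± 0.17) fell. 6 of 35 tested cell cycle genes rose, 11 fell and 18 did not pass (6 and 10 adjusted over the list alone). Cell cycle genes had a median of -0.19 (camera adjusted p = 0.48), and 6 rose and 11 fell of 35 without PBS 3. Kif23 (-1.14 ± 0.22), E2f1 (-1.02 ± 0.21) and Cenpa (-0.98 ± 0.26) fell and Tyms (1.16 ± 0.19) rose.

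**Figure D3:**
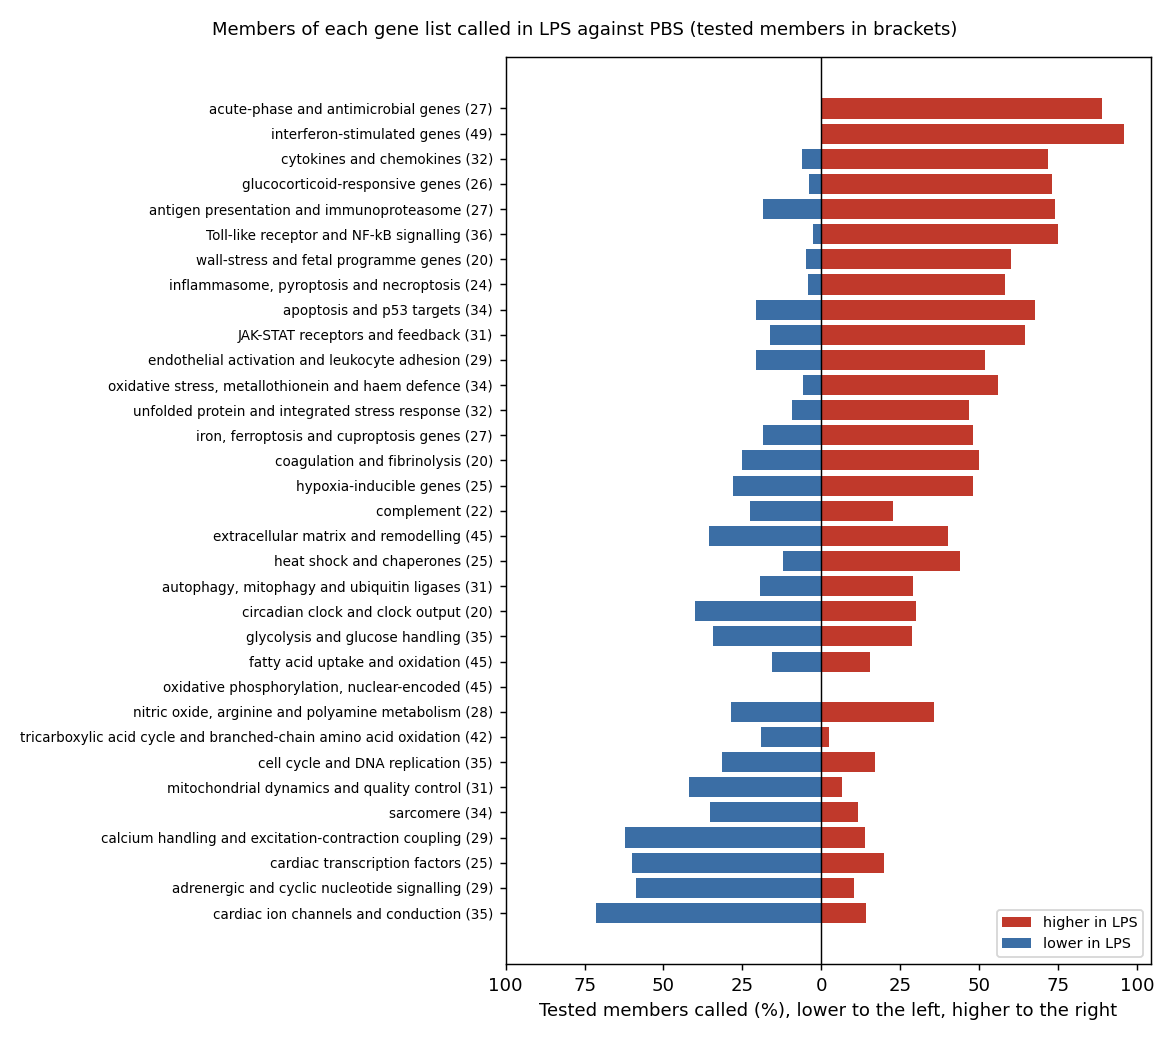
Percent of the tested members of each of 33 gene lists that rose (red, to the right) or fell (blue, to the left) in LPS against PBS hearts, with the number tested in brackets and lists in order of their median log2 fold change. The interferon-stimulated list has 47 of 49 members higher and the respiratory chain list 0 of 45 called.

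Most neutrophil and monocyte markers rose, and most macrophage, fibroblast, mural and Schwann cell markers fell. Several neutrophil markers, among them Lcn2, S100a8, S100a9, Ngp and Il1r2, and the monocyte markers Hp and Chil3 are also in the acute-phase and antimicrobial list. The results of these lists are therefore not independent. Shared members were left out only among gene lists and among marker lists, so that this overlap stayed. 11 of 15 tested neutrophil markers rose, 0 fell and 4 did not pass (13 and 0 adjusted over the list alone). Neutrophil markers had a median of 2.10 (camera adjusted p = 0.000898, and adjusted p = 0.537 with an estimated correlation), with PBS 3 at 69%, and 13 rose and 0 fell of 15 without PBS 3. With Lcn2, they included Ngp (4.29 ± 0.61), Il1r2 (4.01 ± 0.50) and Trem1 (3.22 ± 0.55). S100a8 and S100a9, abundant in neutrophils, were at 10.8 ± 12.7 CPM in PBS and 45.6 ± 13.1 CPM in LPS hearts, and 14 ± 15.6 CPM in PBS and 63.8 ± 14.4 CPM in LPS hearts, and both rose, as S100a8 (2.07 ± 0.76) and S100a9 (2.18 ± 0.74). The call of S100a8 was lost without PBS 2, PBS 4, LPS 1, LPS 2 or LPS 5 (adjusted p from 0.0503 to 0.0726) and that of S100a9 without PBS 4 (adjusted p = 0.0539). 9 of 13 tested monocyte markers rose, 1 fell and 3 did not pass (9 and 1 adjusted over the list alone). Monocyte markers had a median of 1.43 (camera adjusted p = 0.0143, and adjusted p = 0.519 with an estimated correlation), with PBS 3 at 71%, and 10 rose and 1 fell of 13 without PBS 3. Hp (3.34 ± 0.78), F10 (2.75 ± 0.43) and Chil3 (2.42 ± 0.51) rose and Ccr2 (-1.98 ± 0.25) fell. 0 of 16 tested macrophage markers rose, 11 fell and 5 did not pass (0 and 11 adjusted over the list alone). Macrophage markers had a median of -1.24 (camera adjusted p = 0.0143, and adjusted p = 0.519 with an estimated correlation), with PBS 3 at 29%, and 2 rose and 11 fell of 16 without PBS 3. Cx3cr1 (-4.07 ± 0.41), Lyz2 (-2.38 ± 0.23), Cd163 (-2.0 ± 0.23) and Csf1r (-1.66 ± 0.13) fell, with Csf1r at 75.2 ± 11.4 CPM in PBS and 23.8 ± 3.5 CPM in LPS hearts. 0 of 12 tested fibroblast markers rose, 9 fell and 3 did not pass (0 and 9 adjusted over the list alone). Fibroblast markers had a median of -0.96 (camera adjusted p = 0.0144, and adjusted p = 0.519 with an estimated correlation), with PBS 3 at 53%, and 0 rose and 9 fell of 12 without PBS 3. The examples were Col1a1 (-1.40 ± 0.26), Pi16 (-1.28 ± 0.22), Lum (-1.24 ± 0.34) and Col1a2 (-1.21 ± 0.15). 0 of 12 tested smooth muscle and pericyte markers rose, 10 fell and 2 did not pass (0 and 10 adjusted over the list alone). Smooth muscle and pericyte markers had a median of -1.17 (camera adjusted p = 0.00253, and adjusted p = 0.519 with an estimated correlation), with PBS 3 at 30%, and 0 rose and 10 fell of 12 without PBS 3. Vtn (-2.10 ± 0.11), Kcnj8 (-1.45 ± 0.17), Notch3 (-1.33 ± 0.14) and Cnn1 (-1.43 ± 0.51) fell, and the call of Cnn1 was lost without PBS 2, PBS 4, LPS 1 or LPS 3 (adjusted p from 0.0595 to 0.0798). 0 of 5 tested Schwann and neural markers rose, 4 fell and 1 did not pass (1 and 4 adjusted over the list alone). Schwann and neural markers had a median of -2.35 (camera adjusted p = 0.0471, and adjusted p = 0.519 with an estimated correlation), with PBS 3 at 27%, and 0 rose and 6 fell of 7 without PBS 3. Gfra3 (-2.87 ± 0.39), Kcna1 (-2.62 ± 0.21) and Sox10 (-1.97 ± 0.39) fell, and the list missed the threshold with upper-quartile scaling (adjusted p = 0.0806) and with a replicate block (adjusted p = 0.0526).

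**Figure D4:**
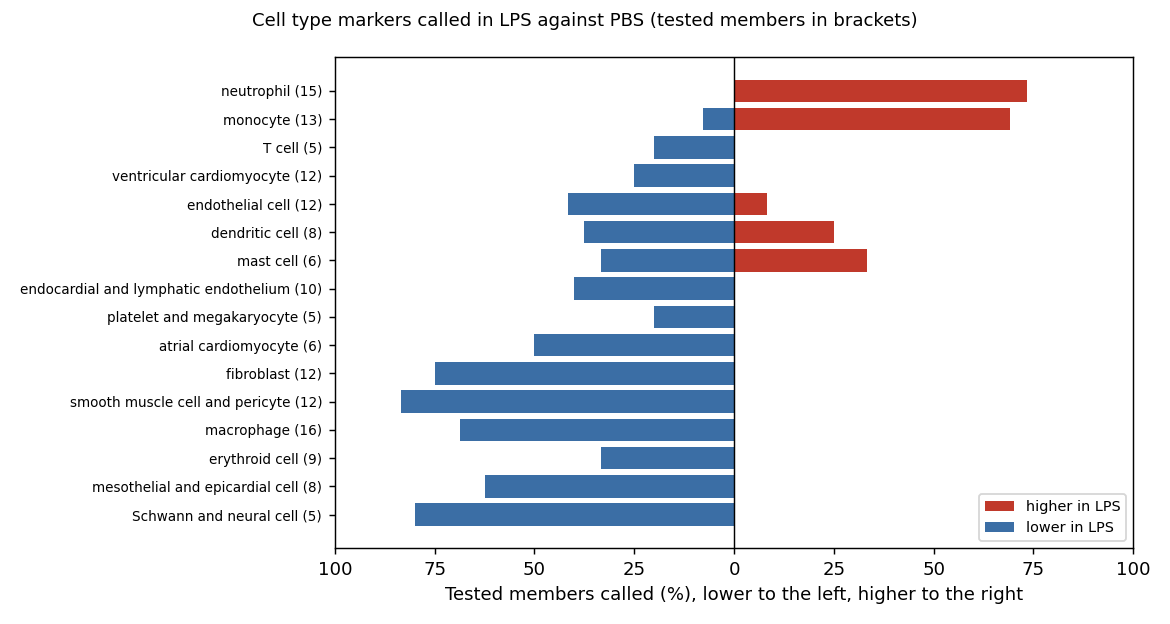
Percent of the tested markers of each cell type that rose (red, to the right) or fell (blue, to the left) in LPS against PBS hearts, for the 16 lists with at least 5 tested members (number in brackets). Neutrophil markers have 11 of 15 higher and macrophage markers 11 of 16 lower.

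The other marker lists did not pass camera. 0 of 12 tested ventricular cardiomyocyte markers rose, 3 fell and 9 did not pass (0 and 3 adjusted over the list alone). Ventricular cardiomyocyte markers had a median of -0.17 (camera adjusted p = 0.199), with PBS 3 at 118%, and 0 rose and 5 fell of 12 without PBS 3. With library totals 0 rose and 6 fell. That list passed without PBS 3 (adjusted p = 0.0433), but not with an estimated correlation (adjusted p = 0.748 with all libraries, and adjusted p = 0.458 without PBS 3). Besides Myh6 and Pln, Actc1 (-1.61 ± 0.38), cardiac actin, fell. 0 of 6 tested atrial markers rose, 3 fell and 3 did not pass (0 and 3 adjusted over the list alone). Atrial markers had a median of -0.84 (camera adjusted p = 0.223), with PBS 3 at 53%, and 0 rose and 3 fell of 6 without PBS 3. With Myl7 and Kcnj3, Dkk3 (-1.51 ± 0.40) fell. 1 of 12 tested endothelial markers rose, 5 fell and 6 did not pass (1 and 5 adjusted over the list alone). Endothelial markers had a median of -0.19 (camera adjusted p = 0.239), and 3 rose and 5 fell of 12 without PBS 3, with a median of -0.08. With upper-quartile scaling 0 rose and 6 fell, and with library totals 0 rose and 6 fell. With Tek, Aqp1 (-1.60 ± 0.17) and Cav1 (-1.27 ± 0.17) fell and Tie1 (0.45 ± 0.15) rose, a call lost without PBS 4 or LPS 5 (adjusted p from 0.0501 to 0.0563), and with upper-quartile scaling or library totals. 0 of 10 tested endocardial and lymphatic markers rose, 4 fell and 6 did not pass (0 and 4 adjusted over the list alone). Endocardial and lymphatic markers had a median of -0.60 (camera adjusted p = 0.239), with PBS 3 at 37%, and 0 rose and 5 fell of 10 without PBS 3. Cytl1 (-2.12 ± 0.51), Ccl21a (-1.91 ± 0.34), Vwf (-1.02 ± 0.34) and Prox1 (-0.54 ± 0.10) fell, and the call of Vwf was lost without PBS 5 (adjusted p = 0.0587). 0 of 8 tested mesothelial and epicardial markers rose, 5 fell and 3 did not pass (0 and 7 adjusted over the list alone). Mesothelial and epicardial markers had a median of -2.11 (camera adjusted p = 0.0605), with PBS 3 at 7%, and 0 rose and 7 fell of 8 without PBS 3. That list passed without PBS 2 (adjusted p = 0.0176), without LPS 5 (adjusted p = 0.0223) and with no filter on low counts (adjusted p = 0.0396), but not with an estimated correlation (adjusted p = 0.676, and adjusted p = 0.665 without PBS 3). Lrrn4 (-3.15 ± 0.59), Krt19 (-3.09 ± 0.71), Muc16 (-2.51 ± 0.55) and Upk3b (-2.15 ± 0.52) fell. 2 of 8 tested dendritic cell markers rose, 3 fell and 3 did not pass (2 and 3 adjusted over the list alone). Dendritic cell markers had a median of -0.21 (camera adjusted p = 0.983), with a shift of -0.36 in PBS 3 and 0.12 in LPS, and 2 rose and 3 fell of 8 without PBS 3. Their median and mean (0.23) differed in sign. Batf3 (2.61 ± 0.32) and Ccr7 (2.15 ± 0.53) rose and H2-Aa (-1.33 ± 0.43) and H2-Ab1 (-0.88 ± 0.29) fell, and the call of H2-Ab1 was lost without PBS 4 (adjusted p = 0.052). 2 of 6 tested mast cell markers rose, 2 fell and 2 did not pass (2 and 2 adjusted over the list alone). Mast cell markers had a median of -0.45 (camera adjusted p = 0.904), and 2 rose and 2 fell of 6 without PBS 3. Their median and mean (0.16) differed in sign. Hdc (3.40 ± 0.57) and Kit (1.31 ± 0.17) rose and Mcpt4 (-1.62 ± 0.51) and Cma1 (-1.23 ± 0.44) fell, and the call of Cma1 was lost without PBS 2, PBS 4, LPS 1, LPS 2, LPS 3 or LPS 4 (adjusted p from 0.0567 to 0.089). 0 of 9 tested erythroid markers rose, 3 fell and 6 did not pass (0 and 2 adjusted over the list alone). Erythroid markers had a median of -1.29 (camera adjusted p = 0.248), with PBS 3 at 119%, and 0 rose and 8 fell of 9 without PBS 3. Bpgm (-1.29 ± 0.42) fell. 0 of 5 tested platelet markers rose, 1 fell and 4 did not pass (0 and 1 adjusted over the list alone). Platelet markers had a median of -0.81 (camera adjusted p = 0.466), with PBS 3 at 148%, and 0 rose and 3 fell of 5 without PBS 3. Gp1ba (-0.62 ± 0.12) fell. 0 of 5 tested T cell markers rose, 1 fell and 4 did not pass (0 and 0 adjusted over the list alone). T cell markers had a median of 0.24 (camera adjusted p = 0.77), with a shift of -0.61 in PBS 3 and 0.15 in LPS, and 0 rose and 1 fell of 5 without PBS 3, with a median of 0.10. Cd4 (-1.19 ± 0.45) fell, and the call of Cd4 was lost without PBS 2, PBS 4, PBS 5, LPS 2, LPS 4 or LPS 5 (adjusted p from 0.0557 to 0.111). Lists with under 5 tested members had no set test. Natural killer markers rose in 3 of 4 (Ccl5 (3.73 ± 0.95), Gzmb (3.10 ± 0.52) and Klrk1 (1.54 ± 0.41)), with PBS 3 at 70%, and without PBS 3, where 4 rose of 5, that list passed (camera adjusted p = 0.0433), but not with an estimated correlation (adjusted p = 0.458). Of B cell markers, 1 of 2 fell, or 2 with upper-quartile scaling or library totals (Ebf1 (-1.19 ± 0.09)), with PBS 3 at 64%. Without PBS 3, 3 of 3 fell, which added Cd79a (-2.64 ± 0.51, adjusted p = 0.000535) and Cd79b (-1.65 ± 0.50, adjusted p = 0.0108). In adipocyte markers 1 of 4 fell, or 2 with those scalings and 1 without PBS 3 (Scd1 (-0.73 ± 0.22)), and the single lung marker tested rose (Napsa (1.27 ± 0.28)), with PBS 3 at 24%, as did 1 of 2 without PBS 3. 0 of 3 thymus markers passed, the most abundant being Satb1 at 21.6 ± 2.77 CPM in PBS and 21.4 ± 3.27 CPM in LPS hearts, and 0 of 2 skeletal muscle and liver markers, with Ckm at 1888 ± 325 CPM in PBS and 1834 ± 159 CPM in LPS hearts; by DESeq2 these counts were 0 and 0, and 0 and 0 had an unadjusted p under 0.05. PBS 3 stood at 131% for thymus markers, of which 1 of 3 fell without it, Arpp21 (-1.69 ± 0.65, adjusted p = 0.0356), and 0 of 2 skeletal muscle and liver markers passed without it, with a shift of -0.54 in PBS 3 and -0.10 in LPS. Cd79a, Cd79b and Arpp21 were chosen after their values were seen.

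The share of the counts taken by several gene classes differed between the groups. Interferon-stimulated genes took 0.288% ± 0.327 of the counts in PBS and 2.38% ± 0.231 in LPS hearts (SD, n = 5, exact permutation test, two-sided, adjusted p = 0.0132), with PBS 3 at 0.87% and the other PBS libraries between 0.108% and 0.18%. Acute-phase and antimicrobial genes took 0.117% ± 0.157 of the counts in PBS and 1.01% ± 0.107 in LPS hearts (SD, n = 5, exact permutation test, two-sided, adjusted p = 0.0132), with PBS 3 at 0.397%. Sarcomere genes took 10.4% ± 1.4 of the counts in PBS and 8.28% ± 0.21 in LPS hearts (SD, n = 5, exact permutation test, two-sided, adjusted p = 0.0298), with PBS 3 at 8.39%, inside the LPS range. The 10 genes with the highest mean, led by Myh6 and Mb, took 11.7% ± 1.5 of the counts in PBS and 8.57% ± 0.308 in LPS hearts (SD, n = 5, exact permutation test, two-sided, adjusted p = 0.0132). Haemoglobin genes took 0.599% ± 0.741 of the counts in PBS and 0.223% ± 0.107 in LPS hearts (SD, n = 5, exact permutation test, two-sided, adjusted p = 0.238), a difference of -0.377 percentage points that became -0.0466 without PBS 5. The smallest unadjusted p that the assignments of 10 libraries allow is 0.00794. Copies of the alpha globin gene share reads, so that only their sum is given. The mean distance of a library from its group centre was 39.6 ± 13 in PBS and 29.5 ± 4.36 in LPS hearts on the log2 scale over all tested genes (SD, n = 5, exact permutation p = 0.0714, two-sided), a difference of -10.1 that was -0.542 without PBS 3 (exact p = 0.849). It passed without PBS 1, PBS 4, PBS 5 or LPS 2 (exact p from 0.0159 to 0.0476).

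Of 33 gene lists, 17 passed camera with its preset correlation (13 higher, 4 lower), and of 16 marker lists 6 passed (2 higher, 4 lower). 0 of these calls held with a correlation estimated from the data, where the lowest unadjusted p was 0.0615 and 0.0966, and by fry, which tests a list by itself, 24 and 10 passed. Gene lists that passed by fry and not by camera were hypoxia, chaperone, clock, endothelial activation, coagulation, mitochondrial dynamics and sarcomere genes (fry adjusted p from 5.52e-05 to 0.0443). Marker lists that did so were atrial, endothelial, endocardial and lymphatic, and mesothelial (fry adjusted p from 0.00327 to 0.0219). Camera gave as many gene lists in 27 of 100 splits of the 10 libraries into 5 and 5, and as many marker lists in 37 of 100. Part of the LPS effect stays in the other splits, so that these numbers do not measure chance alone.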

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

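The tests of PBS 3 and of the marker pattern were chosen after the results were seen. For 534 sets of 5 libraries (a named gene, a list mean, a share or a distance within a group) the gap between the highest or lowest library and its neighbour was divided by the range of the group. 68 values lay above 0.71, where chance gives about 1 in 20, or 27, and 45 of them were PBS 3 and 23 another library.

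LPS 2 lay above its group with a ratio of 0.77 for Calhm6, 0.77 for Lamp2, 0.88 for Ctsl, 0.73 for Myh7, 0.8 for the mean of oxidative phosphorylation, nuclear-encoded and 0.76 for the mean of the marker list platelet and megakaryocyte. LPS 3 lay above its group with a ratio of 0.79 for Tapbpl, 0.76 for Zc3h12a and 0.87 for Slc16a3. PBS 1 lay above its group with a ratio of 0.81 for the mean of heat shock and chaperones. PBS 3 lay above its group with a ratio of 0.72 for Lipg, 1 for Hamp, 0.82 for Serpina3g, 0.84 for Igtp, 0.84 for Gbp6, 0.8 for Irgm1, 0.75 for Tap1, 0.81 for Nlrc5, 0.85 for Zc3h12a and 0.72 for Mlkl. Further ratios of PBS 3 above the rest were 0.75 for Icam1, 0.83 for Angptl4, 0.79 for Pdk4, 0.73 for Adamts4, 0.84 for Clpx, 0.72 for Per1, 0.83 for Cdkn1a, 0.77 for Tnf, 0.82 for Myh7 and 0.73 for the mean of interferon-stimulated genes. More such ratios for PBS 3 above the others were 0.82 for the mean of Toll-like receptor and NF-kB signalling, 0.72 for the mean of JAK-STAT receptors and feedback, 0.81 for the mean of inflammasome, pyroptosis and necroptosis, 0.73 for the mean of fatty acid uptake and oxidation, 0.77 for the mean of autophagy, mitophagy and ubiquitin ligases, 0.85 for the mean of glucocorticoid-responsive genes, 0.91 for the share of interferon-stimulated list, 0.95 for the share of acute-phase and antimicrobial list and 0.83 for the distance to the group centroid. PBS 5 lay above its group with a ratio of 0.76 for the mean of the marker list endocardial and lymphatic endothelium, 0.77 for the mean of the marker list erythroid cell, 0.83 for the mean of the marker list platelet and megakaryocyte and 0.9 for the share of haemoglobin genes. LPS 1 lay below its group with a ratio of 0.73 for Tnf. LPS 2 lay below its group with a ratio of 0.82 for Col5a1. LPS 4 lay below its group with a ratio of 0.8 for Xirp1, 0.75 for Asns, 0.73 for Gadd45g and 0.91 for the mean of the marker list neutrophil. LPS 5 lay below its group with a ratio of 0.74 for Colq. PBS 3 lay below its group with a ratio of 0.77 for Asb2, 0.76 for Klhdc8a, 0.74 for Arhgef19, 0.82 for Lingo3, 0.74 for Ifngr2, 0.77 for Cacnb2, 0.77 for Hspb3, 0.72 for Hlf, 0.89 for Cenpa and 0.83 for H2-Aa. Further ratios of PBS 3 below the rest were 0.78 for H2-Ab1, 0.79 for the mean of tricarboxylic acid cycle and branched-chain amino acid oxidation, 0.81 for the mean of calcium handling and excitation-contraction coupling, 0.75 for the mean of the marker list ventricular cardiomyocyte and 0.74 for the mean of the marker list atrial cardiomyocyte.

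PBS 3 lay 43.6% of the way from the other PBS libraries to LPS. A swap with an LPS library is argued against, because 0 of 5 LPS libraries lay nearer to the PBS mean, and so is its depth, since the position was 43.7% after all libraries were thinned to 11868337 counts. Mixed-in LPS RNA or reads was tested 3 times and cannot be told apart from other causes. In PBS 3, 13 genes lay at least 2-fold beyond all 9 other libraries (11 above, 2 below). A blend of those libraries would lie between them. Among these genes, Myh7 was at 442 CPM, with at most 46.6 in the other PBS and 84 in the LPS hearts. Mixing of these libraries alone does not give such genes. PBS 5 had as many (13), so that the count neither favours nor excludes mixing. LPS shares read from higher and lower genes differed by 14.8 points (15.1 in PBS 5), as mixing predicts. The quartile range of the shares was 35 points against a bound of 26, which goes against mixing (LPS 2 alone had 43.6). How the 3 values were to be weighed was settled only after they were seen. A single wrong label or a sample from outside stays open, and no biological explanation was tested.

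Most neutrophil (11 of 15) and monocyte (9 of 13) markers rose and most mural (10 of 12), fibroblast (9 of 12) and macrophage (11 of 16) markers fell, list calls that were lost with an estimated correlation (adjusted p from 0.519 to 0.537). Plain dilution by leukocyte RNA would lower these as much as ventricular cardiomyocyte markers. Their difference from those changed by -0.68, -0.36 and -0.60 on the log2 scale (exact permutation, largest adjusted p = 0.0476). Without PBS 3 these changes were -0.63, -0.33 and -0.55. The 3 lists thus fell more than the ventricular list, but they were picked because they had fallen in these same libraries. The p does not allow for that choice. The comparison also assumes unaltered transcript levels within cardiomyocytes, so that it does not decide on dilution. Atrial markers, which that test did not use, had a mean log2 fold change of -1.33 and those of ventricular cardiomyocytes one of -0.40. Fewer such cells with unaltered transcripts would lower the markers of a type alike, and 23 of 40 (57.5%) lay more than 2 standard errors from the weighted mean of their list, but the mural list holds 2 cell types and markers shared with other cells would fall less, so that this does not exclude fewer cells. Fewer cells, a lower level of transcripts within cells and dilution cannot be told apart here, and any of them may account for the falls. Whether the rises reflect the number of cells or the level of transcripts within cells was not tested.

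In 100 of 126 splits of the libraries into 5 and 5, the real one included, only the real one gave as many genes (7722, highest other 2161). A grouping unrelated to expression would rank first in about 1 of 100 such draws. Each other split mixes LPS and PBS mice within a side, which widens the spread there and lowers its gene count. For lists called by camera, 27 splits gave at least 17 gene lists (highest other 25) and 37 gave at least 6 marker lists (highest other 10). Each other split still puts unequal numbers of LPS libraries on its sides, so that part of the LPS effect stays in its contrast. The number of lists can therefore not be judged this way, and chance is neither excluded nor shown for it.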

How the results depend on the processing

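The estimated correlation without PBS 3 and the list counts without PBS 3 were chosen after the data were seen, and the other alternatives before. Depth, at 11868340 to 14048111 counts per library, limits genes of low count. Genes called numbered 5999 with an adjusted p of 0.01, 7873 with DESeq2 (32 adjusted p not given), 8744 with voom weights, 7750 with size factors, 8107 with no filter and 7593 with 1 CPM in 5 samples. Tested against a log2 fold change of 1, 1553 genes passed (728 higher, 825 lower), and with a fold change of at least 1 added to the main test 2927 (1325 higher, 1602 lower), both by construction. Increases numbered 2369 with log2(TPM + 1), 2361 with log2(TPM + 0.1) and 2675 with log2(FPKM + 1), against decreases of 3512, 3491 and 4317, and the cause was not tested. Upper-quartile scaling gave 3068 higher and 4874 lower and library totals 2764 and 5019, where each scaling moves all genes of a library by its own construction. With each library left out in turn, 7179 to 8430 genes were called (3530 to 4284 higher, 3623 to 4146 lower), with 15 to 20 gene lists and 6 to 8 marker lists. With an estimated correlation 0 gene lists and 0 marker lists passed, and with PBS 3 left out as well 1 and 0. Marker lists by fry numbered 10, a test of a list by itself. For these the cause was not tested. Myh7 turned to a called increase of 0.629 without PBS 3, where it stood at 442.4 CPM, and no other reversal passed the threshold on either side. Log2 fold changes of 5 genes took the other sign in at least 1 alternative. Atp5b was 0.081 and became -0.053 (upper quartile), -0.072 (totals), -0.025 (log2(TPM + 1)), -0.025 (log2(TPM + 0.1)), -0.069 (log2(FPKM + 1)). Satb1 was -0.013 and became between -0.106 and 0.04 with each library left out. Ckm was -0.042 and became between -0.132 and 0.033 with each library left out. Nppa was 0.047 and became -0.084 (upper quartile), -0.104 (totals), -0.014 (replicate block), -0.122 (log2(TPM + 1)), -0.123 (log2(TPM + 0.1)), -0.165 (log2(FPKM + 1)) and between -0.256 and 0.284 with each library left out. Myh7 was -1.088 and became 0.32 (voom), 0.017 (replicate block) and between -1.338 and 0.629 with each library left out. Of the lists, 7 took the other direction in at least 1 alternative, at the following adjusted p. The complement list was at 0.8164 and became 0.8911 (fry) and between 0.4285 and 0.9901 with each library left out. The nitric oxide, arginine and polyamine metabolism list was at 0.9924 and became 0.9861 (replicate block), 0.6801 (shared members left out), 0.8876 (estimated correlation less PBS 3) and between 0.8144 and 0.987 with each library left out. The fatty acid uptake and oxidation list was at 0.7891 and became 0.9133 (estimated correlation less PBS 3) and between 0.5037 and 0.9763 with each library left out. The glycolysis and glucose handling list was at 0.7992 and became 0.6801 (shared members left out), 0.9339 (estimated correlation less PBS 3) and between 0.5987 and 0.8911 with each library left out. The extracellular matrix and remodelling list was at 0.7304 and became 0.946 (shared members left out). The dendritic cell list was at 0.983 and became 0.904 (no filter), 0.7507 (estimated correlation less PBS 3) and between 0.7474 and 0.985 with each library left out. The mast cell list was at 0.9038 and became between 0.7546 and 0.9688 with each library left out. The cause was not tested. Of 212 named genes, 131 had the same direction and call in every alternative. Over all named genes and alternatives 4428 values had the same direction and call, 149 lost the call, 12 gained it and 24 changed direction, and for lists 730, 54, 28 and 21. The spread difference was -3.265 over the 500 genes with the highest mean (exact p = 0.0318), -9.935 from the group median (exact p = 0.246), and from -13.57 to -0.5421 with each library left out, where PBS 3 sets the smallest. Same-numbered libraries correlated at 0.16, -0.36, 0.22, -0.2 and -0.17 in their deviations from the group means, and only numbers 1 and 3 matched best with their own. These values show no clear pairing of the mice by number, but they were not tested and do not exclude a weak one. With the replicate number as a block, 7077 genes (3553 higher, 3524 lower), 17 gene lists and 5 marker lists passed, the list of Schwann and neural markers not being among them (adjusted p = 0.0526). Of the named genes, 11 lost their call with this block, Bdh1 among them (adjusted p = 0.096). The planned share of counts without mitochondrially encoded genes was not run, as 0 such genes were in the table used.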

Other observations

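Gene families were formed from shared symbol stems, and their tests chosen, after the data were seen, and 17 of 236 passed camera (14 higher, 3 lower), 0 with an estimated correlation. Among the families that passed as higher, 26 rose and 0 fell of 34 Ddx genes, 33 rose and 1 fell of 54 Eif genes, 10 rose and 0 fell of 11 Utp genes, 6 rose and 0 fell of 8 Nop genes and 7 rose and 0 fell of 8 Rrp genes. Likewise, 7 rose and 0 fell of 10 Srsf genes, 12 rose and 0 fell of 49 Rpl genes, 11 rose and 0 fell of 14 Psmd genes, 21 rose and 4 fell of 35 Rbm genes and 9 rose and 0 fell of 19 Nup genes. Of all 13186 tested genes 3806 rose and 3916 fell. The share of Rpl genes that rose was not above that of all genes, and only their lack of falls stood out. Ddx genes encode RNA helicases, Utp, Nop and Rrp genes processing factors of ribosomal RNA and Psmd genes proteasome subunits. The remaining families that passed as higher had symbols of defence and cytokine genes, where 9 rose and 0 fell of 9 Gbp genes, 12 rose and 0 fell of 15 Ifi genes, 8 rose and 1 fell of 10 Cxcl genes and 21 rose and 7 fell of 42 Il genes. Passing as lower, 0 rose and 8 fell of 8 Cbx genes, 5 rose and 18 fell of 31 Col genes and 1 rose and 10 fell of 16 Tspan genes, where Cbx genes encode chromobox proteins and Col genes collagens. Without PBS 3, 17 families passed, and these did not include Rpl (adjusted p = 0.162), Rbm (adjusted p = 0.0535) and Nup (adjusted p = 0.0695). Those gained were Mrpl (2 higher and 23 lower of 49, adjusted p = 0.0103), Parp (8 higher and 1 lower of 12, adjusted p = 0.0249) and Kcnj (1 higher and 7 lower of 8, adjusted p = 0.0105), the last of which had too few tested members with all libraries. The medians of the 17 families that passed with all libraries kept their sign with size factors, upper-quartile scaling and library totals, while the counts that rose and fell moved, among others, for Psmd to 7 and 0 with upper-quartile scaling and 5 and 0 with library totals and for Rbm to 19 and 7 with upper-quartile scaling and 17 and 7 with library totals. As many families passed in 46 of 100 splits (highest other 42). The other splits still hold unequal numbers of LPS libraries on their sides, so that they do not decide whether chance gave the number of families. Ribosomal protein genes have many near-identical pseudogenes, so that counts of Rpl genes are uncertain.

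PBS 3 also held genes at least 2-fold above all 9 other libraries, and those named here were chosen after their values were seen. These included Fos at 139.5 CPM (3.95 to 32.9 in the other PBS and 14.6 to 32.1 in the LPS hearts), Fosb at 41 CPM (0.669 to 8.13 in the other PBS and 2.08 to 3.48 in the LPS hearts), Egr1 at 347 CPM (64.8 to 141 in the other PBS and 88.9 to 147 in the LPS hearts), Nr4a1 at 119.9 CPM (6.84 to 26.7 in the other PBS and 27.3 to 59.1 in the LPS hearts), which are immediate early genes. Besides Myh7, another was Acot1 at 109 CPM (20.8 to 29.9 in the other PBS and 17.5 to 40.8 in the LPS hearts).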
